A study of Mus musculus with 4 samples.

How the data were processed

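Dissociated lung cells of wild-type and Sdc1-/- C57BL/6 mice were measured without treatment and 21 days after bleomycin, 1 library per group. Per the labels, DAPI-negative immune (CD45+), endothelial (CD31+), epithelial (Epcam+) and stromal (negative for all of these) cells of 3 animals were sorted, mixed and run on the 10x 3 prime v2 kit. The deposited matrices hold counts, UMIs per gene and cell barcode, for barcodes the authors had already called as cells. Per the submitters' processing notes they were made with Cell Ranger against mm10. All 4 matrices list 31053 genes, and the 2 wild-type matrices also hold 3 rows of hashtag antibody counts each, which were kept apart from the genes.

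Cells with at least 300 genes and at most 10% mitochondrial UMIs were kept: 4267 of 4523 barcodes in WTD0, 5664 of 6132 in Sdc1D0, 5889 of 6465 in WTBleoD21 and 4281 of 4623 in Sdc1BleoD21. Scrublet, run per library through scanpy 1.11.5 with a score threshold of 0.2, called 60, 153, 91 and 67 of these as doublets, which were left out. The 4207, 5511, 5798 and 4214 cells used had medians of 4957, 4705, 5876 and 6244 UMIs. All cells were clustered together in Python 3.11.15 on log-normalised counts: 2100 variable genes, from which mitochondrial, ribosomal and sex-linked genes and Sdc1 were excluded, 40 principal components, 15 neighbours, and Leiden clustering (leidenalg 0.10.2) of the shared-neighbour graph at resolution 1. No batch correction was applied, so libraries can separate in the clustering. Of 41 clusters, 36 were named from marker lists fixed before the data were examined and merged into 23 classes, and the remaining 5 were left unnamed. A name needed a mean marker score of at least 1 and at least 3 detected markers, with no close second class. Alveolar and activated fibroblast lists were joined as parenchymal fibroblast-like, classical and non-classical monocyte lists as monocyte-like, AT1 and transitional lists as AT1-like, and smooth muscle and pericyte lists as mural-like. Some genes that named clusters are also reported below for the same class, such as Fabp1, Inmt, Tnc and Sftpc, and they make up part of the identity lists. Their values are therefore not independent of the naming.

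UMIs were summed over the cells of a class in a library and divided by the class total to give CPM. Log2 ratios between 2 libraries used a prior of 0.5 UMI, with exact conditional binomial 95% intervals, and shares of cells have exact binomial intervals. These intervals hold counting error only and no difference between animals. A class was compared with at least 50 cells in each library. The 25 gene lists, fixed before the data were examined, were summarised by the median log2 ratio of members with at least 10 UMIs, with an interval from 1000 Poisson draws and a percentile among 10000 random lists matched on expression within 50 ranks each side. The free RNA check list, among these 25, held markers of many cell types. It was applied whole, so in a class it can include that class's own genes, such as Col3a1 and Inmt in fibroblast-like cells. Genes were ranked by size where they had at least 50 UMIs and 50 CPM and at least 0.1 of the level of the highest class. The 4 comparisons were bleomycin in wild type, bleomycin in Sdc1-/-, and Sdc1-/- against wild type at day 0 and at day 21. Scaling to the class total left the median of all genes off 0 in some classes: for bleomycin in wild type at -0.24 in alveolar macrophage-like, 0.15 in AT2-like and 0.20 in T cell-like cells, and for bleomycin in Sdc1-/- at -0.18 in alveolar macrophage-like and 0.16 in T cell-like cells.

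The plan fixed before the data were examined held no test, because the labels did not show that cells of single animals could be told apart. The test of bleomycin in wild type was added after the hashtag counts were seen. Each tag was taken as an animal. Tag counts were divided by the background of each tag, and a cell was given to its highest tag where that had at least 10 counts and was at least 5 times the next, which called 84.3% of WTD0 and 78.3% of WTBleoD21 barcodes. An earlier calling rule, a mixture model per tag, missed many fibroblast and AT2 cells and was replaced. Tagging was uneven: 96.9% and 93.9% of AT2-like cells were tagged at day 0 and day 21, and 50.4% and 38.7% of parenchymal fibroblast-like cells. Classes with at least 50 cells in each of the 6 animals were tested, which left 4, with 247125 to 4532554 UMIs per animal and class. UMI sums per animal were tested in edgeR 4.0.16 (R 4.3.3) with TMM scaling, its default low-count filter and the quasi-likelihood F test, with p adjusted by Benjamini-Hochberg to a false discovery rate of 0.05. The SE printed with a log2 fold change is the size of that change divided by the square root of F. It is an approximation that rests partly on dispersion shared across genes, not on the spread of the 3 animals alone. For gene lists the adjustment was repeated over the list alone. Sdc1-/- libraries carry no hashtags, so their values are set beside the 3 wild-type animals (at least 20 cells each) without a test, and differences between the bleomycin responses of the genotypes were not tested. For list medians, a range given for wild-type animals holds the median of each animal against the others of its own library. It is not the ratio of Sdc1-/- to that animal.

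The methods were tested on simulated data. Intervals of log2 ratios held the true value in 96.1% to 96.8% of simulated genes. The animal-level test recovered 58% to 83% of genes changed 2-fold and 92% to 100% of those changed 4-fold, with 2.75% to 8.52% of calls false over the 4 classes, so the share of false calls can exceed the 0.05 aimed at.

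Alternatives fixed before the data were examined were no cell filter, doublets kept, clustering resolution 0.5 or 2, each library clustered on its own, median-of-ratios scaling, cells thinned to 1000 UMIs, the mean of per-cell CPM, free RNA subtracted, 5 CPM added to each value, and a minimum of 1 or 50 UMIs for list members. The share of free RNA was estimated from markers of other cell types. Chosen after seeing the data were tagged wild-type cells only, each wild-type animal left out in turn, DESeq2 1.42.0, its size factors in edgeR, and no low-count filter. Also chosen after seeing the data were the doublet threshold, the thresholds for naming clusters, the merging of classes, the minimum of 50 cells per animal, the markers of other cell types, the rule and window for genes near Sdc1, and which genes and lists are named. For bleomycin in wild type, Marco, Cdkn1a, Mki67, Top2a and Saa3 were set aside for a time after their alternatives had been seen, and were put back. Numerical work used numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9. No deposited matrix was left out.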

Results

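Gene expression was measured in single cells of dissociated C57BL/6 mouse lung with the 10x 3 prime v2 assay, in 4 libraries. They held untreated wild-type lung (WTD0), untreated Sdc1-/- lung (Sdc1D0), and wild-type (WTBleoD21) and Sdc1-/- lung (Sdc1BleoD21) taken 21 days after bleomycin, a drug that injures the alveoli and is used to model lung fibrosis. Each library combined cells of 3 animals, sorted as immune, endothelial, epithelial and stromal cells and recombined at the bench, so cell classes were compared only within their compartment. The deposited matrices held 4523, 6132, 6465 and 4623 cell barcodes, in that order, with 23814437, 29674929, 42154027 and 31189495 UMIs and medians of 4695, 4438.5, 5462 and 5953 UMIs per barcode. After filters and removal of called doublets, 19730 of 21743 barcodes were used. The Y-linked gene Ddx3y lay between 90.5 and 108 CPM in the 4 libraries and Xist between 0.402 and 2.20. No group had a second library. The wild-type libraries carried counts of 3 hashtags each. The labels do not say what a tag marks; each was taken as 1 of the 3 animals, and all values per animal rest on this. Only bleomycin in wild type had a test between animals; all other values are given without a test, with 95% intervals that cover counting error alone.

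Sdc1, syndecan-1, a cell-surface heparan sulfate proteoglycan, was the deleted gene (ENSMUSG00000020592, mm10 chromosome 12, 8771323 to 8793715). In AT2-like cells, the alveolar type 2 cells that make surfactant, Sdc1 stood at 263 CPM in WTD0 and 18.6 in Sdc1D0, a log2 ratio of -3.82 (-4.01 to -3.64). At day 21 it stood at 352 CPM in WTBleoD21 and 17.9 in Sdc1BleoD21, a log2 ratio of -4.29 (-4.56 to -4.04). In AT1-like cells, the flat gas-exchange epithelium, the day 21 ratio was -4.70 (-5.24 to -4.24), and in parenchymal fibroblast-like cells the day 0 ratio was -2.77 (-3.97 to -1.84). Sdc1 was lower in Sdc1-/- in all 7 classes measured at day 0 and in all 13 measured at day 21. Over all cells it took 3567 UMIs in WTD0, 297 in Sdc1D0, 4488 in WTBleoD21 and 232 in Sdc1BleoD21. A UMI of Sdc1 was seen in 80.7% of 1621 AT2-like cells of WTD0, 12.4% of 1936 of Sdc1D0, 94.1% of 527 of WTBleoD21 and 16.4% of 721 of Sdc1BleoD21, at median depths of 8000, 7345.5, 11381 and 9540 UMIs. In alveolar macrophage-like cells, a class not known for Sdc1, the shares were 5.16%, 0.760%, 9.47% and 0.940% at median depths of 3568, 3124, 6720 and 5343 UMIs. With every cell thinned to 1000 UMIs the AT2-like shares were 22.6%, 1.55%, 29.96% and 1.11%, with 4, 2, 3 and 2 shallower cells left out, and the alveolar macrophage-like shares were 1.17%, 0%, 1.43% and 0.631%, with 6, 9, 8 and 2 left out. The labels do not give the deleted part of the gene, and a 3 prime tag outside it would check nothing. Sdc2 in parenchymal fibroblast-like cells (log2 ratio 0.02, -0.11 to 0.16; -0.09 over tagged cells without animal 2 of WTD0) and Sdc4 in AT2-like cells (0.16, 0.12 to 0.20) differed little between genotypes at day 0.

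**Figure D1:**
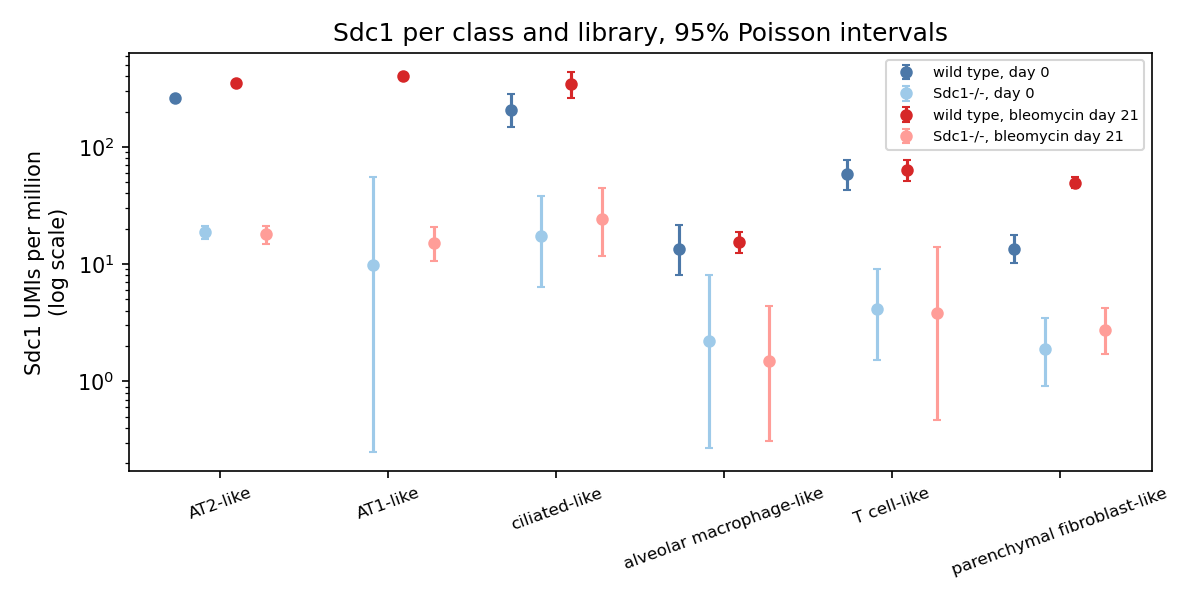
Sdc1 CPM (log axis) in 6 classes of cells, by library, with exact 95% Poisson intervals. AT2-like cells stood at 263 and 352 CPM in the wild-type libraries and at 18.6 and 17.9 in the Sdc1-/- libraries.

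The make-up of each sorted compartment differed between days. AT1-like cells made up 0.235% (0.0640 to 0.5996) of 1705 epithelial cells in WTD0 and 30.9% (28.0 to 34.0) of 957 in WTBleoD21, and 1.07% (0.670 to 1.61) and 25.6% (23.0 to 28.2) in the Sdc1-/- libraries. At a finer clustering (resolution 2) the day 21 shares were 10.8% and 13.3%, so they depend on where clusters were divided. Among immune cells, NK cell-like cells made up 12.6% in WTD0 and 1.07% in WTBleoD21, and 13.3% and 0.987% in Sdc1-/-. Dendritic cell-like cells made up 5.81% and 17.7% in wild type and 6.13% and 14.6% in Sdc1-/-, and interstitial macrophage-like cells 0.502% and 5.56%, and 0.584% and 5.10%. At day 0, alveolar macrophage-like cells made up 25.0% (22.8 to 27.4) of immune cells in WTD0, with its 3 animals between 22.4% and 27.2%, and 12.8% (11.4 to 14.3) in Sdc1D0. At day 21 they made up 28.1% and 26.2%. Parenchymal fibroblast-like cells made up 76.4% of stromal cells in WTD0, 80.3% in Sdc1D0, 60.6% in WTBleoD21 and 74.2% in Sdc1BleoD21, inside the 57.0% to 76.0% of the 3 WTBleoD21 animals, while adventitial fibroblast-like cells, which lie around vessels and airways, made up 12.8%, 11.5%, 24.7% and 14.9%. Tagged cells of the 3 WTBleoD21 animals gave 9.58% to 17.4% for the latter class, of which 20.5% was tagged, so no direction between genotypes is given for either class at day 21. Lymphatic-like cells made up 33.9% (29.8 to 38.2) of 513 endothelial cells in WTBleoD21 and 18.4% (15.3 to 21.9) of 553 in Sdc1BleoD21. Among tagged cells of the 3 WTBleoD21 animals they made up 3.81% to 10.8%, below the Sdc1BleoD21 share, and only 15.5% of the lymphatic-like cells there carried a tag, so no direction is given. Cells in unnamed clusters made up 2.64%, 2.09%, 2.85% and 2.33% of the 4 libraries. The sort sets these denominators, so a share says nothing about cell numbers in the lung.

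Bleomycin in wild type asked which genes differ 21 days after injury. In alveolar macrophage-like cells (349 at day 0, 845 at day 21), Spp1, the secreted matrix protein osteopontin, rose by 4.89 ± 0.215 on the log2 scale (SE, n = 3 animals per day; 313 ± 144 to 7995 ± 749 CPM, mean ± SD; adjusted p = 5.33e-10 in edgeR). Trem2, a lipid-sensing receptor, rose by 3.28 ± 0.197, the fatty acid binding protein Fabp5 by 1.45 ± 0.114, and the antigen-presenting genes Cd74 and H2-Aa by 1.66 ± 0.183 and 1.77 ± 0.192. The elastase gene Mmp12 and the complement gene C1qb also rose; with 3 and 2 UMIs at day 0 their pooled log2 ratios were 6.52 (5.19 to 9.02) and 7.82 (6.28 to 11.2), the latter 7.18 without animal 1 of WTD0. Genes of resident alveolar macrophages fell: the lipid-handling genes Fabp1 and Cidec by -3.86 ± 0.276 and -3.10 ± 0.319, Krt79 by -3.76 ± 0.268, the ribonuclease Ear1 by -2.37 ± 0.204, and the chitinase-like Chil3 by -0.42 ± 0.104. The scavenger receptor Marco did not pass (-0.35 ± 0.414, adjusted p = 0.614). It lay at 0.46 without animal 1 of WTD0 and at 0.04 without animal 3 of WTBleoD21.

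By fixed gene list, 16 of 23 tested members of the lipid-associated and fibrosis-associated macrophage list rose and 1 fell (17 and 2 adjusted over the list alone). Of 19 tested resident alveolar macrophage genes, 14 fell and 1 rose (15 and 1 adjusted over the list alone). The 1 that rose did not pass without animal 2 or 3 of WTD0 or animal 3 of WTBleoD21. The pooled medians of these lists were 1.06 (1.02 to 1.28) and -0.997 (-1.12 to -0.88), above and below all 10000 random lists matched on expression. Of 8 tested MHC class II genes 7 rose (8 adjusted over the list alone), and of 20 lipid and cholesterol synthesis genes 9 rose and 2 fell (11 and 3 adjusted over the list alone). Among 10 tested type I interferon genes 8 rose (8 adjusted over the list alone), such as Ifi27l2a at 3.10 ± 0.237 and Isg15 at 4.21 ± 0.918. The interferon count was 5 without animal 2 of WTD0, 3 without animal 1 of WTBleoD21 and 4 without animal 2 of WTBleoD21, and Isg15 ranged from 15.7 ± 3.19 to 255 ± 308 CPM because animal 2 of WTBleoD21 stood far above the others; without it the Isg15 log2 fold change was 2.53. Rsad2 had no UMI at day 0 and 77.3 ± 95.5 CPM at day 21, and its call was lost without any 1 of the WTD0 animals. The free RNA check list, which includes macrophage genes such as Chil3, moved too. Of 19 tested members 9 rose and 5 fell (11 and 5 adjusted over the list alone). The antibody light chain Igkc rose by 3.35 ± 0.15, and 13 of 17 matrix genes rose in these macrophages. Most cells came from cluster 8 at day 0 and cluster 5 at day 21. Another mixture of cells was not told apart from a change within cells, here or in the other tested classes below. In all, 790 genes rose and 654 fell of 7265 tested, 393 and 247 of them at least 2-fold. Of these calls, 632 rising and 618 falling genes reached at least 0.1 of the level of the highest class, the rule used against free RNA. Without animal 3 of WTD0 the total of 1444 was 924, and with DESeq2 882.

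In parenchymal fibroblast-like cells (787 and 803, of which 397 and 311 were tagged and tested), matrix genes rose. Col1a1 and Col3a1, the main fibrillar collagens, rose by 1.51 ± 0.129 and 1.74 ± 0.113 (1239 ± 222 to 4234 ± 234 CPM for Col3a1, adjusted p = 6.83e-08). The matrix glycoprotein Tnc rose by 3.88 ± 0.215, the latent TGF-beta binding protein Ltbp2 by 4.25 ± 0.2, elastin (Eln) by 2.61 ± 0.145 and the collagenase inhibitor Timp1 by 2.64 ± 0.326. Cilp, Fst and the acute-phase gene Saa3 rose by 4.03 ± 0.424, 3.82 ± 0.517 and 3.48 ± 0.507; without animal 2 of WTD0 the Saa3 log2 fold change was 4.33. Fibroblast identity genes fell: the methyltransferase Inmt by -2.55 ± 0.257 (8670 ± 505 to 1533 ± 883 CPM), the glutathione transferase Gsta3 by -3.23 ± 0.287, the amino acid transporter Slc7a10 by -2.99 ± 0.38, the dipeptidase Dpep1 by -2.33 ± 0.18 and the transcription factor Tcf21 by -1.46 ± 0.179. Without animal 3 of WTBleoD21, Inmt fell by -3.13 and Slc7a10 by -3.96. Spp1 rose by 8.58 ± 1.07 to 585 ± 638 CPM, with the pool of all cells at 1522 CPM. Its log2 fold change was 7.05 without animal 1 of WTBleoD21. In WTBleoD21, 563 of 803 fibroblast-like cells held a Spp1 UMI and 185 held at least 3. Spp1 stood far higher in alveolar macrophage-like cells, and how much of its rise in fibroblast-like cells came from free RNA was not tested. Cthrc1 and Postn, matrix genes of activated fibroblasts, were too low at day 0 to be tested, with 2 and 1 UMIs. The pooled log2 ratios were 8.01 (6.48 to 11.4) for Cthrc1 and 7.71 (5.81 to 13.6) for Postn, over tagged cells 6.49 and 5.45, and without animal 1 of WTBleoD21 among these 5.47 and 5.05. Igfbp2 had 2 UMIs at day 0 and a pooled ratio of 7.26 (5.72 to 10.6), or 6.57 and 8.25 over tagged cells without animal 2 or animal 3 of WTD0.

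Of 26 tested matrix genes 20 rose and 0 fell (20 and 0 adjusted over the list alone). Their pooled median was 1.80 (1.77 to 1.83) over all cells and 1.54 over tagged cells. Of 19 lipofibroblast and alveolar fibroblast genes 13 fell and 2 rose (13 and 2 adjusted over the list alone), with a pooled median of -0.82 (-0.89 to -0.76). Of 12 contractile genes 7 rose (9 adjusted over the list alone), including smooth muscle actin Acta2 at 2.22 ± 0.35. Of 13 Wnt pathway genes 7 rose and 1 fell (8 and 1 adjusted over the list alone); the Wnt antagonist Sfrp1 rose by 2.33 ± 0.191 and the ligand Wnt2 fell by -1.07 ± 0.191. Of 19 TGF-beta genes 9 rose and 1 fell (11 and 2 adjusted over the list alone), and all 7 MHC class II genes rose (7 adjusted over the list alone). Of 13 p53 target genes 7 rose and 1 fell (10 and 1 adjusted over the list alone), such as Ccng1 at 1.10 ± 0.197; 4 rose without animal 1 of WTD0. The free RNA check list moved in the same cells: 10 of 19 rose and 6 fell (11 and 6 adjusted over the list alone). It includes fibroblast genes such as Col3a1 and Inmt. Its member Igkc, foreign to fibroblasts, rose by 3.39 ± 0.162. Most cells came from clusters 2 and 12 at day 0 and cluster 4 at day 21. In all, 767 genes rose and 730 fell of 6635 tested, 419 and 266 at least 2-fold, and DESeq2 called 904.

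In AT2-like cells (1621 and 527) Lcn2, an iron-binding acute-phase protein, rose by 2.34 ± 0.114 (744 ± 135 to 4215 ± 685 CPM, adjusted p = 8.81e-13), the chaperone clusterin (Clu) by 1.95 ± 0.192, Lrg1 by 1.80 ± 0.168, the membrane protein Itm2a by 4.36 ± 0.155 and the keratins Krt7 and Krt8 by 1.75 ± 0.125 and 0.53 ± 0.0888. The p53 targets Phlda3, Ccng1 and Bax rose by 3.45 ± 0.215, 1.63 ± 0.141 and 1.08 ± 0.103, whereas Cdkn1a, the p21 cell cycle inhibitor, did not pass (-0.06 ± 0.119, adjusted p = 0.729). Its log2 fold change was 0.10 without animal 1 of WTD0. Pon1, an esterase, fell by -5.01 ± 0.242 (117 ± 30.1 to 4.10 ± 0.529 CPM), Cst8 by -4.12 ± 0.177 and Bex2 by -3.17 ± 0.168. The surfactant gene Sftpc fell by -0.46 ± 0.0515. The desaturase Scd1 rose by 0.34 ± 0.0896, a call lost at clustering resolution 0.5.

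Of 21 transitional epithelium genes 13 rose and 4 fell (14 and 4 adjusted over the list alone), with a pooled median of 0.76 (0.63 to 1.02). Of 17 p53 genes 8 rose (9 adjusted over the list alone), with a pooled median of 0.83 (0.53 to 0.98), and of 11 interferon genes 9 rose (10 adjusted over the list alone). Of 21 lipid and cholesterol synthesis genes 12 fell and 3 rose (14 and 3 adjusted over the list alone). Of 19 AT2 identity genes 8 fell and 3 rose (9 and 3 adjusted over the list alone); their pooled median was 0.06 (0.05 to 0.07) and turned to -0.09 with median-of-ratios scaling. Of 17 endoplasmic reticulum stress genes 5 rose and 5 fell (6 and 5 adjusted over the list alone). Of 20 dissociation stress genes, which respond to tissue digestion, 12 fell (12 adjusted over the list alone), Jun by -0.97 ± 0.11. The free RNA check list, which includes surfactant genes such as Sftpc, moved in these cells. Of its members 8 of 20 went up and 4 down (8 and 4 adjusted over the list alone). Igkc was up by 3.10 ± 0.0936, and 19 of 21 matrix genes were up. Most cells came from cluster 1 at day 0 and cluster 13 at day 21. In all, 1483 genes rose and 1447 fell of 9307 tested, 447 and 368 at least 2-fold, and DESeq2 called 1833. At least 0.1 of the level of the highest class was reached by 1075 of the rising and 1340 of the falling genes.

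In T cell-like cells (281 and 441) the costimulatory receptor Tnfrsf4 rose by 3.47 ± 0.271 (41.0 ± 12.8 to 510 ± 166 CPM, adjusted p = 9.15e-10), Cd83 by 4.00 ± 0.449, the inhibitory receptor Ctla4 by 1.66 ± 0.244 and the growth factor amphiregulin (Areg) by 2.65 ± 0.431, the last lost with DESeq2. Without animal 2 of WTD0 the log2 fold changes of Cd83 and Areg were 4.74 and 4.29. The IL-33 receptor Il1rl1 rose too, with 2 UMIs at day 0 and a pooled ratio of 4.56 (2.98 to 7.94), 3.77 without animal 3 of WTD0. Klf2, Lef1 and Ccr7, genes of naive recirculating T cells, fell by -2.35 ± 0.125, -2.24 ± 0.193 and -2.19 ± 0.135. Of 17 proliferation genes 6 rose (10 adjusted over the list alone); 2 rose without animal 1 or animal 3 of WTD0 and 3 without animal 2 of WTBleoD21. Mki67 rose by 1.04 ± 0.323 (adjusted p = 0.0201), a call lost without each of these 3 animals, and Top2a did not pass (0.60 ± 0.222, adjusted p = 0.0518). Of 16 genes of the free RNA check list 9 rose and 5 fell (10 and 5 adjusted over the list alone). The list includes the T cell gene Cd3e. Igkc rose by 3.27 ± 0.227, and 8 of 9 matrix genes rose. Most cells came from cluster 11 at day 0 and cluster 16 at day 21. In all, 412 genes rose and 400 fell of 3566 tested, and DESeq2 called 462. At least 0.1 of the level of the highest class was reached by 335 of the rising and 383 of the falling genes. At an unadjusted p below 0.05 the counts were 2376 genes in alveolar macrophage-like, 3815 in AT2-like, 2243 in fibroblast-like and 1208 in T cell-like cells. The library and the sequencing run of each day cannot be told apart from bleomycin.

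**Figure D2:**
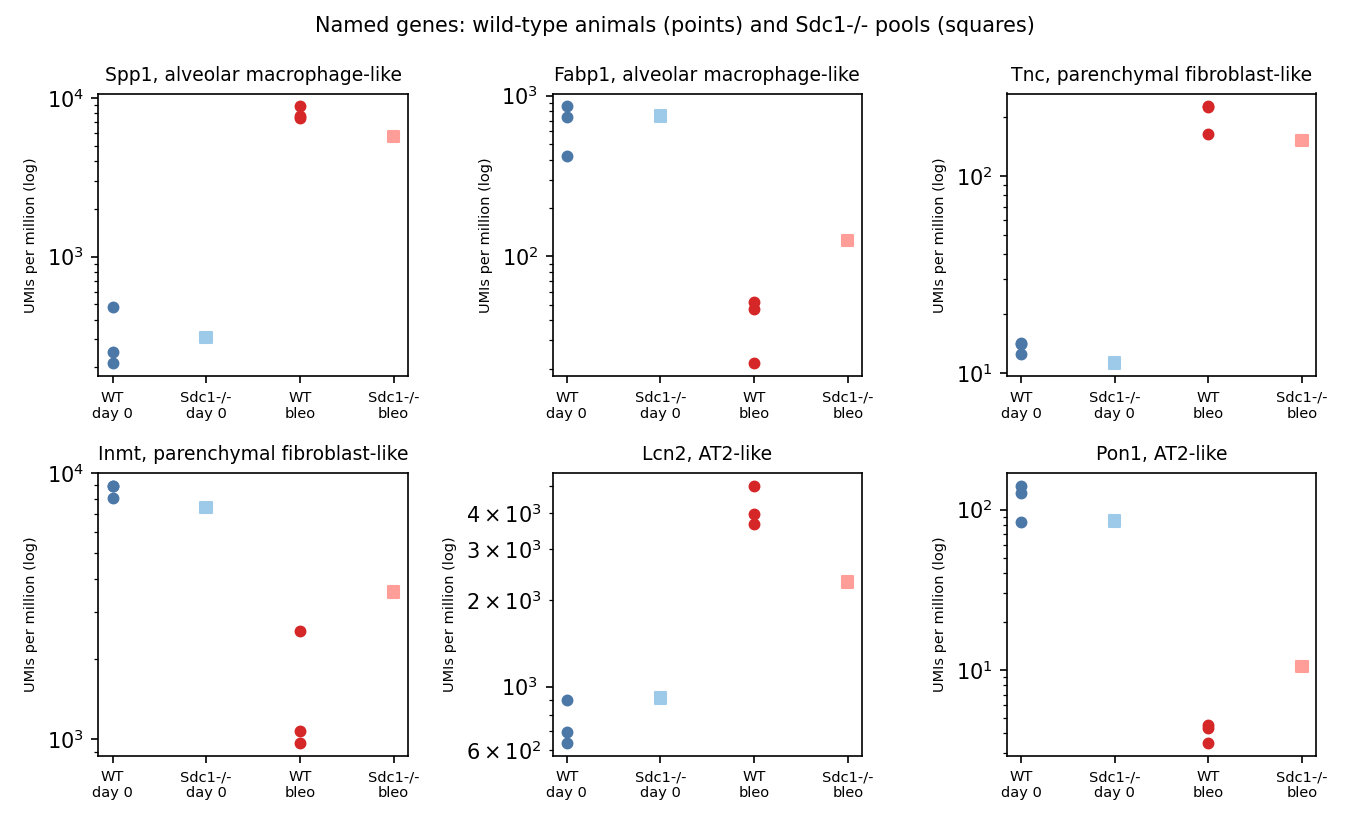
CPM (log axes) of 6 genes in 3 classes of cells, with wild-type animals as points (3 per day, some overlapping) and each Sdc1-/- library as a square. Spp1 in alveolar macrophage-like cells had a mean of 313 at day 0 and 7995 at day 21 over wild-type animals and stood at 5736 in Sdc1BleoD21.

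Other wild-type classes had too few cells per animal for the test, and their pooled values follow. In monocyte-like cells (149 and 437) Ccl4 and Cxcl10, chemokines that draw lymphocytes, were higher at day 21 by 2.03 (1.90 to 2.16) and 2.14 (1.87 to 2.44) on the log2 scale, and by 0.43 and 1.22 without animal 2 of WTBleoD21. Without animal 3 of WTD0, Ccl4 was higher by 1.38. The cytokine and chemokine list had a median of 0.72 (0.68 to 0.95), which was 0.26 without animal 2 of WTBleoD21. In dendritic cell-like cells (81 and 531) the same list had a median of 1.11 (0.52 to 1.23), 0.25 without that animal, and Ccl4 was higher by 2.26 (2.05 to 2.49), 0.10 without it, and 3.22 without animal 1 of WTD0. With each library clustered on its own the list median was 0.24 and Ccl4 0.57. In neutrophil-like cells Ccl3 was higher by 1.503 (1.21 to 1.82), and by 0.79 without animal 2 of WTBleoD21. In adventitial fibroblast-like cells Serpina3n, an acute-phase protease inhibitor, was higher by 2.57 (2.21 to 2.97).

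Bleomycin in Sdc1-/- repeats the contrast without Sdc1, from 1 library per day. In alveolar macrophage-like cells (263 and 319) Spp1 was higher at day 21 by 4.21 (4.04 to 4.39) on the log2 scale and Mmp12 by 5.36 (4.27 to 7.13), 28.3% of its UMIs from 1 of 319 cells, while Fabp1 was lower by -2.58 (-2.79 to -2.37), Krt79 by -2.43 (-2.69 to -2.18) and Cidec by -1.78 (-2.16 to -1.42). In parenchymal fibroblast-like cells (1000 and 990) Saa3 was higher by 6.81 (6.36 to 7.35), Cthrc1 by 6.53 (5.33 to 8.58), 26.1% of its UMIs from 1 of 990 cells, and Tnc by 3.75 (3.38 to 4.17), and Inmt was lower by -1.06 (-1.08 to -1.04). Spp1 there had 4 UMIs at day 0 and 3477 at day 21, and 39.3% of the latter came from 1 cell. In AT2-like cells (1936 and 721) Phlda3 was higher by 3.31 (2.99 to 3.66), Itm2a by 3.11 (2.83 to 3.41) and Lcn2 by 1.34 (1.30 to 1.37), and Pon1 was lower by -3.00 (-3.36 to -2.68). In T cell-like cells (449 and 154) Areg was higher by 3.28 (2.78 to 3.84), Tnfrsf4 by 3.13 (2.81 to 3.47) and Lef1 lower by -0.95 (-1.33 to -0.60), while Ccr7 differed by -0.13 (-0.33 to 0.07).

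The list medians of bleomycin in Sdc1-/- stood beside those of wild type. The fibrosis-associated macrophage list had a median of 1.14 (0.94 to 1.45), against 1.06 in wild type, with 12 of 24 members at least 2-fold higher and 1 lower. With cells thinned it was 0.66 against 1.25, and with free RNA subtracted 0.84 against 1.34, so how near the 2 values lie depends on the setting. The resident alveolar macrophage list had -0.56 (-0.70 to -0.47) against -0.997, a difference of 0.43 (0.25 to 0.57). The matrix list in fibroblasts had 1.15 (1.08 to 1.28) against 1.80, a difference of -0.65 (-0.71 to -0.52), which was -0.40 with tagged wild-type cells and ranged from -0.58 to -0.25 with 1 animal of these left out. Its members included 17 of 30 at least 2-fold higher. The lipofibroblast list had -0.11 (-0.20 to -0.02) against -0.82, and the contractile list 0.73 (0.62 to 0.82) against 1.14. In AT2-like cells the transitional list had 0.33 (0.20 to 0.40) against 0.76, a difference of -0.44 (-0.74 to -0.28); the Sdc1-/- value was 0.14 with cells thinned, with free RNA subtracted or with each library clustered on its own, and the difference -0.76 in the last of these. The p53 list had 0.83 (0.57 to 0.92) against 0.83, and the lipid and cholesterol list -0.08 (-0.13 to 0.01) against -0.36. The interferon list had 0.52 (0.22 to 1.07) against 1.85 in alveolar macrophage-like cells and 0.59 (0.33 to 0.80) against 1.92 in AT2-like cells. MHC class II in alveolar macrophage-like cells had 1.11 (1.03 to 1.48) against 1.45. None of these differences was tested. Most AT2-like cells of Sdc1BleoD21 lay in cluster 1, as at day 0, its fibroblast-like cells in cluster 4 (43.2%, and 85.2% in WTBleoD21) and cluster 2 (40.2%, and 12.5%), and its alveolar macrophage-like cells in cluster 5 (64.9%, and 86.2%) and cluster 8 (30.1%, and 4.38%). Igkc was lower by -2.27 to -0.73 in 9 classes of Sdc1-/- and higher by 2.95 to 3.49 in 9 classes of wild type. The 2 sets share 8 classes and leave out B cell-like cells.

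**Figure D3:**
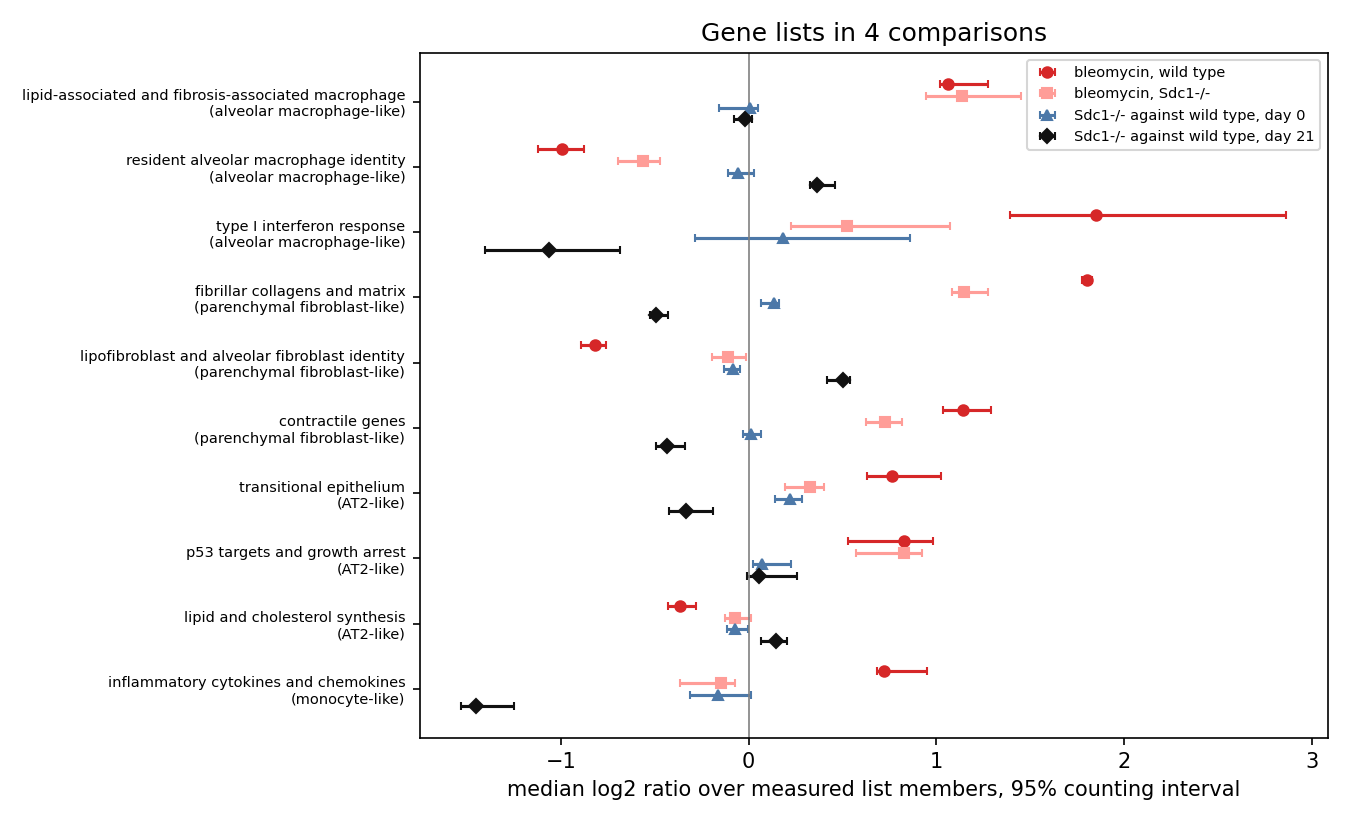
Median log2 ratio over the measured members of 10 gene list and class pairs in 4 comparisons, with 95% counting intervals. In fibroblast-like cells the matrix list stood at 1.80 for bleomycin in wild type and 1.15 in Sdc1-/-, and the lipofibroblast list at -0.82 and -0.11.

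Sdc1-/- against wild type at day 0 asked what the deletion alone changes. Counts of genes that differed in size varied between classes. Of 1525 genes that met the size rule in AT2-like cells, 0 were at least 2-fold higher and 1, Sdc1, was at least 2-fold lower, and of 2434 in parenchymal fibroblast-like cells 0 were either. The other 8 classes had more but fewer UMIs, and these counts are not compared. The ornithine decarboxylase gene Odc1, which starts polyamine synthesis, was lower in fibroblast-like cells by -0.96 (-1.07 to -0.85), in T cell-like cells by -1.99 (-2.34 to -1.65) and in monocyte-like cells by -1.73 (-2.29 to -1.20). The transcription regulator Id2 was lower in AT2-like cells by -0.58 (-0.65 to -0.52) and in NK cell-like cells by -1.09 (-1.30 to -0.89), but higher in monocyte-like cells by 0.45 (0.25 to 0.65) and in neutrophil-like cells by 0.85 (0.33 to 1.43); it was lower in 3 and higher in 2 of 10 classes. Adi1, of the methionine salvage pathway, was higher in AT2-like cells by 0.84 (0.66 to 1.03). In T cell-like cells Gzmb and Ccl5, genes of cytotoxic cells, were higher by 1.78 (1.34 to 2.29) and 1.11 (1.04 to 1.18). In alveolar macrophage-like cells (349 and 263) Csf1r, the receptor for the growth factor CSF1, was higher by 1.10 (0.65 to 1.56), while Spp1 differed by 0.02 (-0.21 to 0.24), and by -0.20 and -0.18 without animal 2 or animal 3 of WTD0. Marco was higher by 0.95 (0.73 to 1.18), at 421 CPM in Sdc1D0 with the 3 wild-type animals at 418, 118 and 138, and by 1.70 without animal 1 of WTD0.

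The transitional list in AT2-like cells had a median of 0.22 (0.14 to 0.28). The 3 wild-type animals, each against the others of their library, lay between -0.12 and 0.12. The syndecan and heparan sulfate list had 0.15 (0.01 to 0.27) and the lipid and cholesterol list -0.07 (-0.12 to 0.00); the latter was 0.05 without animal 2 of WTD0. The AT2 identity list had 0.04 (0.01 to 0.05), and -0.04 with median-of-ratios scaling. In this comparison the median of all genes in AT2-like cells was 0.09, and the AT2-like list medians of this paragraph carry that offset. Extracellular vesicle biogenesis, to which syndecans contribute, had 0.14 (0.07 to 0.17) in AT2-like, -0.06 (-0.12 to 0.06) in fibroblast-like and 0.00 (-0.13 to 0.15) in alveolar macrophage-like cells, where it lay between 0.03 and 0.06 with 1 animal of WTD0 left out. The matrix list in fibroblast-like cells had 0.13 (0.07 to 0.16), the lipofibroblast list -0.08 (-0.13 to -0.05), and in alveolar macrophage-like cells the resident list had -0.06 (-0.11 to 0.03) and the fibrosis-associated list 0.01 (-0.16 to 0.05), between -0.16 and -0.05 with 1 animal of WTD0 left out. The free RNA check list, which includes genes of these classes, had medians of 0.50 (0.36 to 0.73) in AT2-like and 0.78 (0.47 to 0.94) in T cell-like cells.

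Sdc1-/- against wild type at day 21 asked how the injured lung differs without Sdc1. In alveolar macrophage-like cells (319 against 845) the mixture of clusters differed: cluster 8, which held most of the class at day 0, held 30.1% of these cells in Sdc1BleoD21 and 4.38% in WTBleoD21. Over the whole class, and without telling this mixture from a change within cells, resident genes stood higher in Sdc1-/-, Fabp1 by 1.74 (1.48 to 2.01), Krt79 by 1.49 (1.19 to 1.79), Cidec by 1.12 (0.73 to 1.49) and Ear1 by 1.06 (0.90 to 1.22). Fabp1 stood at 125 CPM in Sdc1BleoD21 and at 21.6, 51.8 and 47.1 in the 3 wild-type animals. Cidec was higher by 0.58 without animal 1 of WTBleoD21 and by 1.62 without animal 3. Spp1 was lower by -0.49 (-0.52 to -0.46), at 5736 CPM against 7679.6, 7455 and 8850.4. The resident list had a median of 0.37 (0.32 to 0.46), or 0.68 with cells thinned, with wild-type animals between -0.30 and 0.17, and the fibrosis-associated list -0.02 (-0.08 to 0.02), 0.01 without animal 3. The extracellular vesicle list had 0.12 (-0.01 to 0.19).

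Interferon and cytokine genes were lower in Sdc1BleoD21. In alveolar macrophage-like cells the interferon genes Isg15, Rsad2 and Ifit1 were lower by -2.37 (-2.70 to -2.07), -3.32 (-4.25 to -2.61) and -2.79 (-3.52 to -2.19), and the chemokines Ccl4 and Cxcl10 by -2.81 (-2.96 to -2.66) and -1.89 (-2.08 to -1.72). Animal 2 of WTBleoD21 carried much of the wild-type level: Isg15 stood at 45.2 CPM in Sdc1-/- and at 85.6, 611 and 68.9 in the 3 wild-type animals, and Ifit1 at 10.4 and at 31.3, 209 and 7.77. Without animal 2 the ratios were -0.78 for Isg15, -1.71 for Rsad2, -0.93 for Ifit1, -1.14 for Ccl4 and -0.30 for Cxcl10. The interferon list had a median of -1.07 (-1.41 to -0.68) and ranged from -1.03 to -0.82 with 1 animal left out, with 10 of 19 members at least 2-fold lower and 0 higher. In AT2-like cells it had -0.92 (-1.10 to -0.63), from -1.14 to -0.68 with 1 animal left out. In dendritic cell-like cells Isg15 was lower by -1.67 (-1.88 to -1.47), and by -0.30 without animal 2.

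In monocyte-like cells (243 against 437) Ccl4, Cxcl10 and Cxcl2 were lower by -2.54 (-2.65 to -2.43), -2.57 (-2.80 to -2.35) and -1.47 (-1.55 to -1.39), and without animal 2 of WTBleoD21 by -0.96, -1.69 and -0.37. Ccl4 stood at 581 CPM in Sdc1-/- and at 1598, 6434 and 695 in the wild-type animals. The interleukin-1 receptor antagonist Il1rn was lower by -1.50 (-1.89 to -1.13) and Odc1 by -2.61 (-3.14 to -2.15), Odc1 at 28.6 CPM against 171, 179 and 152. The cytokine and chemokine list in monocyte-like cells had a median of -1.45 (-1.53 to -1.25), and -0.40 without animal 2. The wild-type animals, each against the others of their library, lay between -0.78 and 1.04. In AT2-like cells the list had -1.23 (-1.42 to -1.02), from -1.22 to -1.10 with 1 animal left out, and in neutrophil-like cells -1.23 (-1.86 to -1.01), from -1.42 to -1.21. It had -1.03 (-1.14 to -0.67) in fibroblast-like cells, -0.66 against tagged cells, -0.53 without animal 1 among these and -0.32 with free RNA subtracted. It had -0.53 (-0.71 to -0.43) in alveolar macrophage-like and -0.47 (-0.64 to -0.32) in dendritic cell-like cells, and without animal 2 these were -0.23 and -0.26. Igkc was lower in Sdc1BleoD21 in each of 14 classes, by -3.53 to -2.11, and the estimated share of free RNA in monocyte-like cells was 12.2% in WTBleoD21 and 7.97% in Sdc1BleoD21.

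In parenchymal fibroblast-like cells (990 against 803) alveolar fibroblast genes were higher in Sdc1-/-. Gsta3 was higher by 2.41 (2.22 to 2.61), Dpep1 by 1.86 (1.75 to 1.97), Inmt by 1.47 (1.43 to 1.502) and Tcf21 by 1.29 (1.17 to 1.41), and each lay above all 3 wild-type animals. Inmt, for example, stood at 3577 CPM against 973, 1075 and 2552. Over all cells Spp1 was lower by -1.74 (-1.79 to -1.68), Postn by -1.65 (-1.90 to -1.41), Cilp by -1.33 (-1.49 to -1.16), Fst by -1.15 (-1.31 to -0.99) and Col12a1 by -1.03 (-1.22 to -0.84). Against tagged cells, 38.7% of the class, these were -0.66, -0.31, -0.97, -0.83 and -0.82. Without animal 1 of WTBleoD21 among these cells Spp1 was higher by 1.09, Postn by 0.09, and Cilp, Fst and Col12a1 were lower by -0.71, -0.33 and -0.56. The matrix list had a median of -0.50 (-0.53 to -0.43), with wild-type animals between -0.42 and 0.20, -0.27 against tagged cells and -0.02 against tagged cells without animal 1. The lipofibroblast list had 0.50 (0.42 to 0.54), with wild-type animals between -0.34 and 0.35, 0.31 against tagged cells and 0.26 without animal 1 or animal 2. The contractile list had -0.43 (-0.49 to -0.34), -0.32 against tagged cells and -0.07 without animal 1. The vesicle list had -0.01 (-0.11 to 0.03), and 0.06 without animal 2.

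In AT2-like cells (721 against 527) Bex2 and the chitinase Chia1 were higher in Sdc1-/- by 1.12 (0.96 to 1.29) and 1.18 (1.07 to 1.30), Chia1 by 1.80 without animal 3 of WTBleoD21, and Lcn2, Itm2a and the mucosal chemokine Cxcl17 were lower by -0.83 (-0.86 to -0.80), -0.87 (-1.02 to -0.71) and -0.83 (-0.99 to -0.66). Most AT2-like cells lay in cluster 1 in Sdc1BleoD21 (87.8%) and in cluster 13 in WTBleoD21 (87.5%). The transitional list had a median of -0.33 (-0.42 to -0.19), or -0.65 with each library clustered on its own, with wild-type animals between -0.13 and 0.02 and a range of -0.34 to -0.28 with 1 animal left out. The syndecan and heparan sulfate list had 0.03 (-0.20 to 0.11), and -0.09 and -0.10 without animal 2 or 3. The vesicle list had -0.01 (-0.12 to 0.06), and 0.05 without animal 3. In AT1-like cells (284 against 296) the AT1 identity list had 0.52 (0.44 to 0.58), and the sodium channel subunit Scnn1b was higher by 1.05 (0.76 to 1.35). This class joins AT1 and transitional lists. At resolution 2 its share moved from 30.9% to 10.8% in WTBleoD21 and from 25.6% to 13.3% in Sdc1BleoD21. Another mixture within the class was not told apart from a change within cells. In general capillary-like cells (333 against 256) the MHC class II list had -0.85 (-1.02 to -0.71), with wild-type animals between -0.28 and 0.17. It was -0.82 with free RNA subtracted and -0.57 with doublets kept. The free RNA check list had -0.02 (-0.17 to 0.08), but it includes endothelial genes such as Cldn5, so it is no measure of free RNA from immune cells here. Cd74 was lower by -1.005 (-1.08 to -0.93). As at day 0, Id2 was lower in some classes and higher in others (5 and 3 of 14). Id2 was lower by -0.97 (-1.05 to -0.88) and Adi1 higher by 0.89 (0.64 to 1.16) in AT2-like cells, and Odc1 was lower in T cell-like cells by -2.24 (-2.60 to -1.91). The 3 Sdc1-/- animals of each library were not separated, so no spread between them is known.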

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

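The other splits of animals and the tests of explanations below were chosen only after the results were seen, and the tests with single animals left out replaced a comparison with the spread between wild-type animals whose values had been seen. Several results ran in opposite directions after bleomycin in the 2 genotypes; these differences between genotypes were not tested. They were 6 of 180 pairs of a gene list and a class, and 8 of 69 pairs of a named gene and a class. The gene pairs count Igkc separately in each of several classes. The cytokine and chemokine list was higher at day 21 in wild type and lower in Sdc1-/- in dendritic cell-like cells (1.11 and -0.24, a difference of -1.34) and in monocyte-like cells (0.72 and -0.15, a difference of -0.87). Among its genes, Ccl4 in dendritic cell-like cells differed by -3.04 (2.26 and -0.78), Tnf by -3.47 (2.11 and -1.36) and Ccl3 by -3.23 (1.74 and -1.49), and Cxcl10 in monocyte-like cells by -2.72 (2.14 and -0.57). The wild-type values lean on animal 2 of WTBleoD21: without it Tnf stood at 0.75 and Ccl3 at 0.29. With each library clustered on its own the wild-type values in dendritic cell-like cells were -0.094 for Tnf, -1.57 for Ccl3 and 0.57 for Ccl4. In that setting Tnf and Ccl3 had no Sdc1-/- value. For these 2 genes the opposite direction was thus lost only beside the Sdc1-/- values of the main clustering.

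Igkc, an antibody light chain made by plasma cells, differed by -4.49 in alveolar macrophage-like (3.08 and -1.41), -4.82 in parenchymal fibroblast-like (3.35 and -1.47), -4.57 in AT2-like (3.28 and -1.29) and -4.22 in T cell-like cells (3.49 and -0.73). With free RNA subtracted the wild-type value in fibroblast-like cells was -6.06. Igkc shifted alike in all 9 classes compared outside B cell-like and plasma cell-like cells, by 2.95 to 3.49 in wild type and -2.27 to -0.73 in Sdc1-/-. These Igkc pairs may thus be a single change in the free RNA of the libraries, and are not read as responses of each class. The lipofibroblast list differed by -1.25 in T cell-like (0.94 and -0.31) and -1.18 in dendritic cell-like cells (0.37 and -0.81). It is named for fibroblasts, but it is not wholly foreign here: its member Fabp5 stood at 719 CPM in dendritic cell-like cells of Sdc1BleoD21. MHC class II genes differed by 0.35 in monocyte-like cells (-0.20 and 0.15), with the wild-type value at 0.33 without animal 3 of WTD0. The dissociation stress list differed by 0.44 in parenchymal fibroblast-like cells (-0.40 and 0.04), but the Sdc1-/- value was -0.023 at resolution 0.5 and -0.055 at resolution 2, so the opposite direction was lost.

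For the genes that passed the animal-level test in wild type, the 6 animals were also split in the other ways. Of the 10 splits, the real split was the only 1 as large: 1444 genes in alveolar macrophage-like, 2930 in AT2-like, 1497 in parenchymal fibroblast-like and 812 in T cell-like cells, while edgeR gave 0 in every other split, the highest count. Each other split has animals of both days in both groups, so the day difference itself adds to the spread and holds the count down. The 10 splits are also too few for a share under 0.05, so no conclusion about chance is drawn. All animals of a day shared a library, so this cannot tell bleomycin from the library.

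The genes beside Sdc1 form the first pattern. Odc1 lies 8.77 megabases from Sdc1, Id2 16.3 and Adi1 19.9, and all 3 differed in some classes of Sdc1-/- at both days, Id2 in either direction, but so did Taf10 on another chromosome, lower in 6 of 10 classes at day 0 and 9 of 13 at day 21. Mice made in cells of another strain can keep a stretch of its chromosome around the deleted gene, or loss of Sdc1 could act on these genes. In AT2-like and fibroblast-like cells, with 5 genes noticed earlier left out (these 3, Sdc1 and Taf1b), 9.46% of 74 genes on the first 40 megabases of chromosome 12, which hold Sdc1, differed the same way at both days (7 genes), against 3.51% of 9883 elsewhere. This was rank 1 of 71 windows, with the highest other at 7.53%, which is consistent with a kept stretch. In immune classes 8% of 50 genes did, against 3.94% of 6197, rank 3 of 68 windows with the highest at 10.9%, which settles nothing. The rule and the window were set after other versions had been looked at, among them a stricter rule on single ratios and windows of other widths, so the rank is not a test.

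The lower cytokine and interferon lists in Sdc1BleoD21 form the second pattern, with free RNA, weaker dissociation stress, 1 wild-type animal, or less inflammation at day 21 as explanations. With free RNA subtracted the cytokine median was -1.51 in monocyte-like, -1.59 in AT2-like and -0.32 in fibroblast-like cells. The interferon median in alveolar macrophage-like cells was -1.35. The subtraction took a single share per class and library. For bleomycin in wild type it turned Igkc in fibroblast-like cells from 3.35 to -6.06, so it can take away too much. It did not shrink the medians outside fibroblast-like cells, but it cannot exclude free RNA as a source in any of these classes. The dissociation stress list had -0.13 in monocyte-like cells, the only class in which it was set against this pattern. The limit it was judged by was written after the results were seen. A list median in that class alone cannot exclude dissociation stress as a source. With the most influential wild-type animal left out, the cytokine median was -0.40 in monocyte-like cells, where animal 2 of WTBleoD21 carried much of the level, but -1.10 in AT2-like cells, and the interferon median was -0.82 in alveolar macrophage-like cells. These 2 medians thus stayed below 0 whichever wild-type animal was left out. Leaving out the tagged cells of an animal cannot remove its free RNA from the shared library, and single Sdc1-/- animals could not be left out. A single animal is therefore not excluded as the source, and genotype and library cannot be separated. The immune compartment held 3004 of 5798 cells in WTBleoD21 and 1216 of 4214 in Sdc1BleoD21.

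The third pattern is that identity lists were higher and the matrix list lower in Sdc1BleoD21, with depth, free RNA, 1 wild-type animal, or a milder injury as explanations. The matrix median was -0.39 with cells thinned, so the greater weight of deep cells in the sums alone does not account for it. Thinning keeps the make-up of each cell, so it cannot exclude a difference between cells that goes with their depth. With free RNA subtracted it was -0.54, so that step did not shrink it, but the limits of the subtraction given above hold here too. Against tagged cells, 38.7% of the wild-type ones, it was -0.27, and without animal 1 of WTBleoD21 among these -0.021, so that animal and the loss of untagged cells cannot be told apart as its source. The lipofibroblast median was 0.26 without its most influential wild-type animal, which leaves that open. The resident macrophage median was 0.36, so no single wild-type animal sets the latter. Single Sdc1-/- animals could not be left out, so 1 of them could still set it. A milder or earlier-resolving injury in the Sdc1-/- animals of this library, or another mixture of clusters within a class, would look the same as an effect of the deletion.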

How the results depend on the processing

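The alternatives with DESeq2, other settings of the animal-level test, tagged cells only and single animals left out were chosen after seeing the data; the others were fixed before the data were examined. No paired analysis was possible because the tag numbers of the 2 wild-type libraries name different animals and the Sdc1-/- animals were not separated. Of 2445 alternative values for 173 log2 ratios of genes, 1873 stayed the same within their intervals, 566 changed in size and 6 in direction, where direction was counted only for results whose interval excluded 0. In all 2429 kept their sign. Of 1067 for 72 list medians, 860 stayed, 201 changed in size and 6 in direction, and 1028 kept their sign. Of 685 for 53 animal-level log2 fold changes 669 stayed, and of 220 for 44 shares 157 did. Where a result changed, the cause was not tested. No value could be had for 16 results with each library clustered on its own, 6 with thinned cells and 1 with free RNA subtracted.

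Results that changed direction come first. For bleomycin in wild type, Igkc in fibroblast-like cells was -6.06 with free RNA subtracted, and in dendritic cell-like cells Tnf was -0.094 and Ccl3 -1.57 with each library clustered on its own. The AT2 identity median was -0.091 with median-of-ratios scaling, and -0.042 for Sdc1-/- at day 0. The dissociation stress median of fibroblast-like cells in Sdc1-/- was -0.023 at resolution 0.5 and -0.055 at resolution 2. With 1 animal left out, animal-level log2 fold changes ranged from -0.21 to 0.10 for Cdkn1a in AT2-like cells and from -0.68 to 0.46 for Marco in alveolar macrophage-like cells, and the pooled Marco ratio from -0.95 to 0.23. The MHC class II median in monocyte-like cells ranged from -0.60 to 0.33. For Sdc1-/- against wild type, the AT2 lipid and cholesterol median ranged from -0.14 to 0.055 at day 0, and in fibroblast-like cells at day 21 Postn ranged from -0.66 to 0.091 and Spp1 from -1.05 to 1.09.

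For bleomycin in wild type, the fibrosis-associated macrophage median was 1.35 with median-of-ratios scaling, 1.34 with free RNA subtracted, 0.95 at resolution 2 and 1.003 with each library on its own, and the resident macrophage median was -0.71 with median-of-ratios scaling and -0.87 with each library on its own. The matrix median was 1.75 with no cell filter, 1.83 with doublets kept, 1.63 thinned, 1.75 as the mean of cells, 1.85 with free RNA subtracted, 1.86 at resolution 0.5, 1.96 at resolution 2, 1.85 with each library on its own and 1.54 over tagged cells, and ranged from 1.40 to 1.73 with 1 animal left out. The lipofibroblast median was -0.90 with no filter, -0.92 at resolution 0.5, -0.96 at resolution 2, -0.92 with each library on its own and -0.75 over tagged cells, with a range from -0.82 to -0.67. In AT2-like cells the transitional median was 0.61 with median-of-ratios scaling and 0.63 with free RNA subtracted, and the p53 median 1.04 as the mean of cells and 1.02 with members of at least 1 UMI. DESeq2 called 882 genes in alveolar macrophage-like, 1833 in AT2-like, 904 in fibroblast-like and 462 in T cell-like cells, and with 1 animal left out the alveolar macrophage-like count ranged from 924 to 1276.

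For bleomycin in Sdc1-/-, the fibrosis-associated macrophage median was 0.66 thinned, 0.84 with free RNA subtracted and 0.87 with members of at least 50 UMIs. The resident macrophage median was -0.35 with median-of-ratios scaling and -0.46 thinned, the matrix median 1.36 at resolution 2, and the transitional median 0.14 thinned, 0.14 with free RNA subtracted and 0.14 with each library on its own. The matrix difference between genotypes was -0.74 with free RNA subtracted and -0.40 over tagged cells, with a range from -0.58 to -0.25 over single animals left out, and the transitional difference was -0.76 with each library on its own.

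For Sdc1-/- against wild type at day 0, Sdc1 in AT2-like cells was -4.06 thinned and -3.51 with 5 CPM added. The transitional median was 0.14 with median-of-ratios scaling and 0.30 with each library on its own, and ranged from 0.13 to 0.29 over single animals left out. The matrix median was 0.17 with free RNA subtracted and ranged from 0.050 to 0.15, and the resident macrophage median from -0.12 to -0.040. At day 21, Sdc1 in AT2-like cells was -4.76 thinned and -3.96 with 5 CPM added. The resident macrophage median was 0.30 with median-of-ratios scaling, 0.68 thinned and 0.32 with each library on its own. The matrix median was -0.39 thinned, -0.54 with free RNA subtracted, -0.42 at resolution 2 and -0.27 over tagged cells, with a range from -0.35 to -0.021. The lipofibroblast median was 0.55 with no filter, 0.57 at resolution 0.5, 0.54 at resolution 2, 0.55 with each library on its own and 0.31 over tagged cells, with a range from 0.26 to 0.41. The AT2 transitional median was -0.43 thinned and -0.65 with each library on its own. The monocyte cytokine median was -1.23 as the mean of cells and -1.24 with each library on its own, with a range from -1.61 to -0.40.

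Shares of cells moved with clustering. Alveolar macrophage-like cells made up 22.7% of immune cells in WTD0 with no filter. AT1-like cells made up 10.8% in WTBleoD21 and 13.3% in Sdc1BleoD21 at resolution 2, and 11.3% in Sdc1BleoD21 with each library on its own. Parenchymal fibroblast-like cells made up 55.4% in WTBleoD21 with doublets kept, 55.9% at resolution 0.5 and 57.5% at resolution 2, and in Sdc1BleoD21 64.6%, 64.4% and 60.9%, and 69.1% with each library on its own.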

Other observations

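The tests of explanations above were chosen only after the results were seen, and the values below are given without a test. General capillary-like endothelial cells, which line the alveolar blood vessels, could be compared after bleomycin in Sdc1-/- alone (60 cells at day 0, 333 at day 21). Basement membrane collagens Col4a1 and Col4a2 were higher at day 21 by 1.83 (1.39 to 2.35) and 1.92 (1.32 to 2.67), and the basement membrane list had a median of 0.53 (0.17 to 1.52). The capillary identity list had -0.03 (-0.16 to 0.13) and the endothelial injury list 0.19 (0.08 to 1.10), with 7 of 21 members at least 2-fold higher and 2 lower. In the same cells the AT2 identity list, foreign to endothelium, had -1.34 (-1.44 to -1.10), and the cause was not tested.

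In adventitial fibroblast-like cells a few genes were set beside each other after bleomycin. Saa3, an acute-phase protein, had 0 UMIs at day 0 and 199 at day 21 in wild type, and 1 and 218 in Sdc1-/-, but 33.7% and 28.4% of the day 21 UMIs came from 1 cell, with a UMI in 49 of 327 and 29 of 199 cells. Postn had 0 and 176 UMIs in wild type, and 5 and 90 in Sdc1-/-, where 38.9% came from 1 cell. The estimated share of free RNA at day 21 was 13.5% in wild type and 6.02% in Sdc1-/-. Col1a1 was higher by 1.33 (1.24 to 1.42) in wild type. At day 21 the MHC class II list in these cells was lower in Sdc1-/- by a median of -1.63 (-1.85 to -1.43), with all 8 members at least 2-fold lower. The free RNA check list had -0.47 (-0.70 to -0.32), but it includes fibroblast genes such as Col3a1. It is no measure of free RNA from immune cells here, and how much of the MHC class II difference came from free RNA was not tested. Mesothelial-like cells, which cover the lung surface, had an interferon median of -1.27 (-1.48 to -0.92), and -0.48 (-0.68 to -0.27) for the free RNA check list. The same limit holds for them.

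The data leave 2 things open that a further experiment could settle. Sequencing the chromosome 12 stretch around Sdc1 in these mice would show whether Odc1, Id2 and Adi1 carry variants of another strain. Separate libraries for single Sdc1-/- animals would give the spread that the lower cytokine lists lack.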
